A study of Mus musculus with 3 samples.

How the data were processed

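Cerebella of wild-type mouse embryos were pooled per preparation, dissociated and captured on 10x Genomics Chromium, and the labels list 3 samples (E16 replicates 1 and 2, and E18). The deposited matrices of E16 replicate 1 and E18 hold raw UMI counts per gene and barcode for 28692 genes and all 737280 barcodes of the chemistry, with no normalization and no selection of cells. Cell Ranger, Seurat and the build mm10 are named per the submitters' processing notes, without versions. E16 replicate 2 was not analysed here, as no count matrix of it was among the files used. The labels speak of cell or nucleus suspensions for the series, and of single cells for these samples.

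The groups were the 2 ages with 1 library each, so no test, standard error or count of changed genes was computed. Shares carry exact Clopper-Pearson intervals, and ratios of counts the exact conditional interval of a ratio of 2 Poisson counts, at 95%. These intervals leave out variation between embryos, litters and preparations, and those of summed UMIs also leave out variation between cells.

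Cells were called from the raw matrices. A barcode was kept with UMIs of at least the larger of 1000 and 10% of the 99th percentile of the library's 5000 largest barcodes (1785.57 at E16 and 1844.62 at E18), at least 500 genes and at most 10% mitochondrial UMIs. Of 5740 and 5735 barcodes at the UMI minimum, 298 and 101 were left out by genes and 137 and 166 by mitochondrial share. Doublets were treated by Scrublet per library, as implemented in scanpy, with an expected rate of 0.05 and a simulated ratio of 2, and 108 and 112 barcodes were removed. Kept cells held 37777961 and 39985188 UMIs.

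Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken by their dispersion against a running median of 501 genes of like mean, scaled values were limited to 10, and 30 principal components, 15 neighbours with Jaccard weights and Leiden clustering at resolution 1 with seed 1 gave 37 clusters. Mitochondrial, ribosomal, haemoglobin and sex genes were kept out of the variable genes. Markers of 16 classes were fixed before the data were examined, as were the cell-calling rule, the gene lists, the comparisons, the rule for named genes and most alternatives. The rule that turns markers into a name was settled after the clusters were seen, and several scorings were looked at, under each of which the Purkinje-like cluster had its name. A cluster was named when at least 3 markers and 50% of the class's markers lay at least 1.5-fold over the mean of the clusters and were seen in 20% of its cells. In addition its median depth was at least 50% of the median cell, and its 10 leading genes held no more markers of another class than of its own. A cluster with both Tal2 and Tfap2d, taken as midbrain genes, among its leading genes was not named nuclear neuron-like, a condition written for that cluster. A looser rule, with 3 markers in 10% of cells and no other condition, was run as an alternative.

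Counts of each class with at least 100 cells in both libraries were summed per library and given as CPM. Log2 ratios of E18 over E16 were formed for genes with at least 10 UMIs over both libraries. Genes were named by rule: in Purkinje-like cells the 10 with the highest and the 10 with the lowest ratio, and in other classes 5 each way, among genes with at least 50 CPM and 50 UMIs in 1 library. Mitochondrial, ribosomal, haemoglobin and sex genes were left out, as were genes with over 50 CPM in empty barcodes and under 2 times that level in the class. In Purkinje-like cells 1013 genes were candidates and 2411 were left out as possibly free RNA. Members of fixed lists and markers are named as part of their list, and values of some members are not reported here. Coordinates are from GENCODE vM21 on GRCm38.

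The 16 lists were Purkinje maturation, early Purkinje and migrating neuron, Purkinje subtype, Shh response, Purkinje-derived signals, cell cycle S, cell cycle G2M, granule differentiation, gliogenesis, neurogenic progenitor, synaptic, dissociation stress, glycolysis and hypoxia, cholesterol synthesis, haemoglobin and sex. Marker sets of the classes were read in the same way. A list's median log2 ratio is given with the 95% range of 1000 Poisson redraws and its percentile among 10000 random lists matched on expression in 20 bins. Some genes stand in more than 1 list, such as Foxp2, Ebf2, Calb1 and Slc1a3.

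Free RNA was profiled in empty barcodes around the peak of barcode totals, 136 UMIs at E16 (68 to 204 UMIs, 53119 barcodes) and 206 at E18 (103 to 309 UMIs, 50643 barcodes), which held 13.8% and 18.3% of all UMIs. The first profile, from barcodes of 10 to 100 UMIs, missed this peak and held 368782 and 218106 UMIs. The window was moved after results had been seen, and the first one is kept as an alternative; 18 of the 20 genes named in Purkinje-like cells were the same with it, Rprm and Scg2 taking the other places. In granule neuron-like cells 5 of the 10 named genes were the same, in unipolar brush cell-like cells 8, in granule progenitors and in progenitors or astroglia 9, and in interneurons 10. The share of free RNA in a class was estimated from haemoglobin and Ttr UMIs relative to empty barcodes, leaving out the 5% of cells with the highest share, a trimming also chosen later. It was 8.35% at E16 and 11.8% at E18 in Purkinje-like cells, and 7.26 to 8.78% and 9.00 to 11.9% in the other classes. With every cell of the class included it was 18.2% and 13.7% in Purkinje-like cells, 8.24 to 25.2% in the other classes at E16, and at E18 13.6 to 23.7% but for 165% in interneuron-like cells, which no share can reach. An estimate from the UMIs of an empty barcode per cell, added later, gave 1.84% and 1.99% in Purkinje-like cells.

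For heterogeneity, cells with at least 3000 UMIs were thinned to that depth. The Fano factor of each gene with at least 10 UMIs was ranked among 200 genes of like mean. Genes at the top of the means shared 1 such set, whatever their own mean. For sub-clusters, 50% of UMIs drawn at random gave 1000 variable genes, 10 components, 10 neighbours and Leiden clusters at resolution 1, and genes with at least 20 UMIs in the remaining part were read from it. Shares of cells with Foxp1 or Foxp2 were taken at 3000 UMIs, and the mean over every thinning, the draws of equal cell numbers, the per-cell Purkinje call and the clustering without markers were added after results had been seen. That call took cells with 3 or more Purkinje markers at 3000 UMIs. The calls that free RNA would give outside the Purkinje-like cluster, with independent Poisson draws from the empty-barcode profile at the highest share estimated for a class (8.78% and 11.9%), were 23.0 at E16 and 79.8 at E18, and 0.510 and 2.63 at the UMIs of an empty barcode per cell. List medians within clusters of at least 100 cells per library, and with the E18 clusters of a class weighted to their share of the class at E16, were added later too.

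The steps were tested on simulated data with 200 changed genes. In Purkinje-like cells the interval held the true ratio for 96.0% of 11015 genes, log2 changes of 1 and 2 were recovered at medians of 0.98 and 2.00, and a raised list of 20 genes reached percentile 100. These counts were Poisson draws, as the interval assumes, with no variation between cells. They thus check the computation and not whether the interval is wide enough for real cells. With cells of 1 profile, 4.72% of genes at E16 and 4.78% at E18 lay above the 95th Fano percentile. Of 200 genes raised 8-fold in 20% of cells, 46% and 43% did. The other settings were a minimum of 2000 UMIs, no doublet removal, at most 5% mitochondrial UMIs, resolutions 0.5 and 2, components centred per library, TMM scaling, subtraction of free RNA, no filter or 50 UMIs per gene, thinning to 3000 or 1500 UMIs, and 5 seeds.

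The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.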

Results

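The series holds droplet single-cell RNA counts from whole cerebella of wild-type mouse embryos at embryonic days 16 (E16) and 18 (E18). The cerebella of each preparation were pooled before dissociation, and RNA was captured on 10x Genomics Chromium. The labels list 3 samples, of which 2 libraries are compared here, 1 per age; E16 replicate 2 was not analysed here. The E16 library held 53628123 unique molecular identifiers (UMIs, each 1 captured RNA molecule) over 480027 barcodes, and the E18 library held 59131172 UMIs over 516547 barcodes. After cell calling, 5197 cells were kept at E16 with a median of 6850 UMIs and 2531 genes. At E18, 5356 cells were kept with a median of 7104.5 UMIs and 2590.5 genes. With 1 library per age, no difference could be set against a spread between replicates and none was tested. Intervals are 95% and cover counting error only, so a difference between the libraries can stem from age, litter or preparation.

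The first comparison asked which cell classes made up the cerebellum at each age. Purkinje-like cells, the class of the cortex's output neurons, made up 6.91% of the E16 library (359 of 5197 cells, exact Clopper-Pearson interval 6.23 to 7.63%) and 1.64% of the E18 library (88 of 5356 cells, 1.32 to 2.02%). Their share in the E18 library was 0.238 times that at E16 (0.186 to 0.301). Granule neuron-like cells were more abundant in the E18 library, at 22.7% against 15.2%, a ratio of 1.49 (1.36 to 1.63), while the summed UMIs of their fixed markers in the same kept cells had a ratio of 1.05 (1.03 to 1.07). Cells of the oligodendrocyte lineage, marked by Olig1, Olig2 and Pdgfra, made up 0.577% at E16 and 1.90% at E18, a ratio of 3.30 (2.18 to 5.14).

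GABAergic interneuron-like cells, marked by Pax2, were less abundant in the E18 library, at 4.65% against 7.39%, a ratio of 0.629 (0.534 to 0.740). Granule progenitor-like cells, which carry Atoh1, differed little, at 12.5% and 14.1%, a ratio of 1.13 (1.02 to 1.26). The neural progenitor or astroglia-like class made up 12.9% and 14.0%, a ratio of 1.09 (0.982 to 1.21). Glutamatergic nuclear neuron-like cells, named from Lhx9, Meis2 and Slc17a6, numbered 71 at E16 and 10 at E18, a ratio of 0.137 (0.0628 to 0.266). Under a looser naming rule, which let in a further cluster with Lhx2, Lhx9, Tal2 and Tfap2d, that nuclear neuron ratio was 0.769. The main rule kept this cluster out because Tal2 and Tfap2d were taken as midbrain genes, so it may not hold cerebellar nuclear neurons. The unipolar brush cell-like ratio of 1.27 (1.07 to 1.51) turned to 0.956 under the looser rule. Unipolar brush cell markers in kept cells had a ratio of 0.946 (0.908 to 0.986). Of the non-neural classes, microglia or macrophage-like cells made up 1.37% and 1.74%, endothelial-like cells 0.269% and 0.523%, and meningeal fibroblast-like cells 0.885% and 1.18%. Erythroid-like cells made up 1.06% and 0.672%, and choroid plexus-like cells 0.50% and 0.299%. No cluster was named ependymal-like or brainstem or midbrain neuron-like, which sets no limit on such cells, since ependymal markers had 202 UMIs in kept cells at E16 and 460 at E18.

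**Figure D1:**
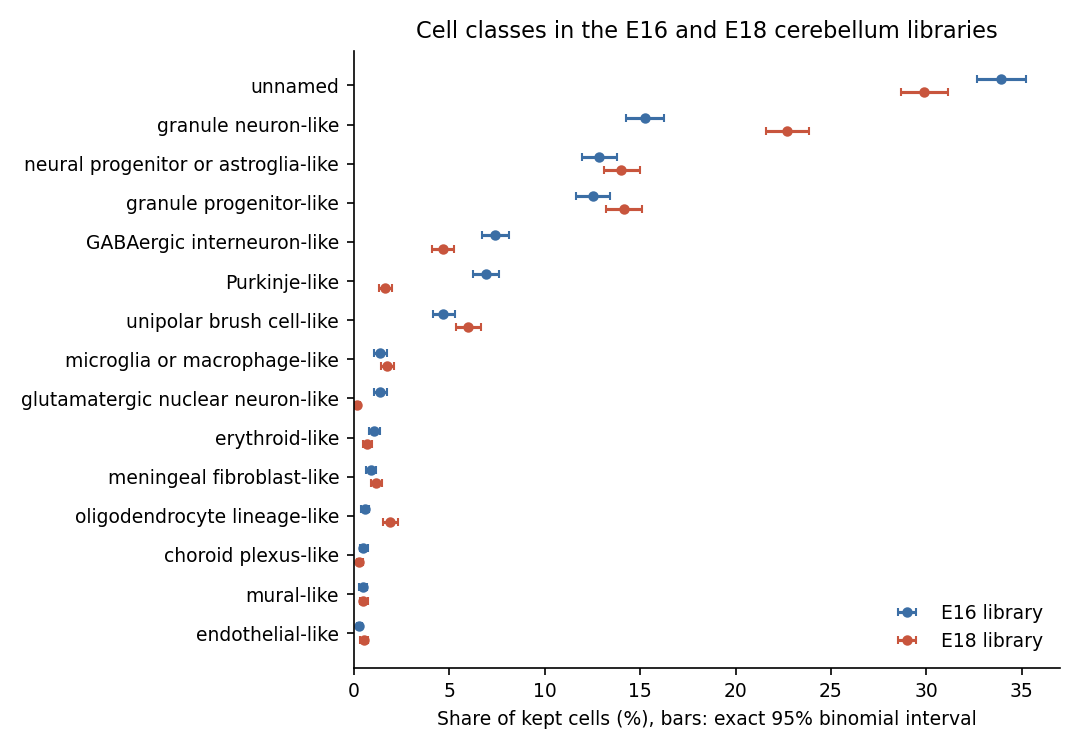
Percent of kept cells in each named class in the E16 and E18 libraries, with exact 95% intervals as bars. The Purkinje-like share was 6.91% at E16 and 1.64% at E18, and the granule neuron-like share 15.2% and 22.7%.

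Unnamed clusters held 33.9% of the E16 and 29.9% of the E18 cells. Among them, 7 clusters carried markers of a class but were kept out by naming thresholds set after the data were seen. A cluster led by Cxcl14, Barx2 and Otx2 held 3.85% and 3.90% of cells at E16 and E18, and 1 with Neurog2 and Ptf1a, factors of neural progenitors, held 2.37% and 2.88%. A cluster with granule markers and Tlx3 held 2.62% and 2.56%, 1 with Foxj1 and Aldoc held 2.71% and 1.92%, and 1 with Olig1, Olig2 and Slc6a11 held 0.885% and 2.61%. A cluster of low depth held 0.827% and 0.691%, and a cluster with Lhx2, Lhx9, Tal2 and Tfap2d held 0.212% and 1.03%. The Purkinje-like class was a single cluster, with Pcp2, Pcp4, Car8, Calb1 and Foxp2 among its leading genes, and neither rule brought in a further cluster.

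Purkinje RNA was also measured without calling cells. Summed UMIs of Pcp2, Car8, Calb1, Foxp2 and Rora stood at 338 CPM (UMIs scaled to a fixed total within the same set of cells or barcodes) in the kept cells at E16. They stood at 227 at E18, a ratio of 0.672 (0.655 to 0.691). CPM of different sets do not compare amounts. Kept cells held 12777 of these UMIs at E16 and 9094 at E18, and empty barcodes 12234 and 20371. The kept-cell ratio counts cells of every class, so 0.672 is not the ratio of the Purkinje-like class. A larger part of the Pcp2, Car8 and Calb1 UMIs of kept cells lay outside that class at E18 than at E16. In barcodes of at least 500 UMIs, before the other filters, the same genes made up 363 and 280 CPM, a ratio of 0.771 (0.753 to 0.789). Over every barcode they made up 580 and 623 CPM, a ratio of 1.07 (1.06 to 1.09), and in empty barcodes 1658 and 1884 CPM, a ratio of 1.14 (1.11 to 1.16). The genes differed: over every barcode the ratio was 0.583 for Foxp2, 0.749 for Rora, 1.10 for Pcp2, 1.44 for Car8 and 1.65 for Calb1. Of these, Calb1, Car8 and Pcp2 also had a higher CPM within Purkinje-like cells of the E18 library.

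**Figure D2:**
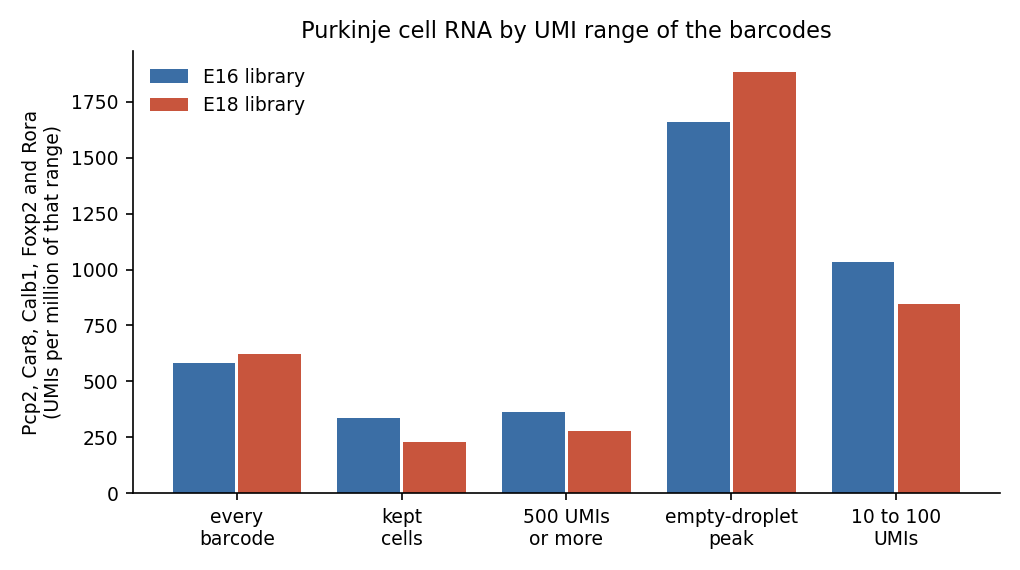
CPM of Pcp2, Car8, Calb1, Foxp2 and Rora summed, in barcodes grouped by their UMIs and scaled within each group, for the E16 and E18 libraries. The E18 to E16 ratio was 0.672 in kept cells and 1.14 in empty barcodes.

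The second comparison asked which genes differed in Purkinje-like cells, the subject of the series title. Among the 1013 candidate genes left by the naming rule, the highest ratios were those of Itpka and Itpr1. Itpka, a kinase of inositol trisphosphate, stood at 7.80 CPM at E16 and 72.4 CPM at E18, a 9.28-fold difference (log2 3.21, 2.49 to 3.99). Its log2 ratio was 1.51 with every cell thinned to 3000 UMIs. Thinned ratios of single genes come from 1 random draw and carry no interval. In another draw at that depth Itpka had means of 0.034 UMIs per cell at E16 and 0.224 at E18. Itpr1, the receptor that opens the calcium store, stood at 33.0 and 213 CPM (log2 2.69, 2.32 to 3.06). Inpp5a, a phosphatase of the same messenger, had a log2 ratio of 1.5. The surface glycoprotein Thy1 was 3.19-fold higher in the E18 library (62.4 and 199 CPM, log2 1.67, 1.37 to 1.98), and Gabbr2, a subunit of the GABA-B receptor, had a log2 ratio of 1.42. The other genes with the highest ratios were the antisense transcript Gm15594 (2.0, and 2.57 in thinned cells, close to the 2.59 of Itpr1 there), the kinase Nrk (1.89), B3galt2 (1.64), Ehbp1l1 (1.52) and Plcxd2 (1.41).

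Cdh9, a cadherin and a member of the Purkinje subtype list, had the lowest ratio of the candidates at full depth, at 28.7 against 81.7 CPM (log2 -1.51, -2.14 to -0.93). The semaphorin receptor Nrp2 stood at 78.0 and 31.9 CPM (log2 -1.29), and Ebf2, a transcription factor of early neurons, at 224 and 106 CPM (log2 -1.07, -1.39 to -0.77). Hs6st2, a heparan sulfate sulfotransferase, had a log2 ratio of -1.44, the growth factor Tgfb2 -1.23, the receptor phosphatase Ptprd -1.07 and the corepressor Skor1 -1.01. Log2 ratios were -0.98 for Grin2b, a subunit of the NMDA receptor, which stood at -2.82 in thinned cells, and -0.91 for Hook1, a microtubule linker. Glra2, a glycine receptor subunit, had a log2 ratio of -1.13, which turned to 0.064 in thinned cells.

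**Figure D3:**
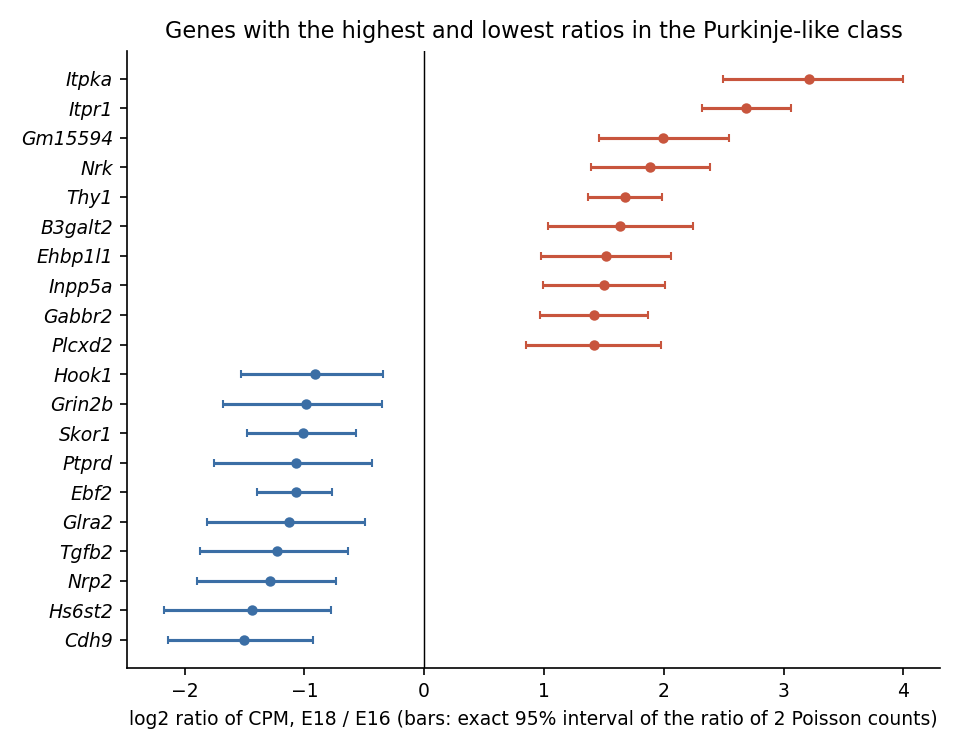
Log2 ratio of CPM, E18 over E16, for the 10 genes with the highest and the 10 with the lowest ratios among the 1013 candidates of the Purkinje-like class. Bars are exact 95% intervals of a ratio of 2 Poisson counts. Itpka stood highest at 3.21 and Cdh9 lowest at -1.51. In 1 random draw of cells thinned to equal depth these were 1.51 and -1.07, with Itpr1 highest at 2.59 and Grin2b lowest at -2.82. That order holds for that draw only.

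By identity and position on GRCm38 (GENCODE vM21, positions from 1), Itpka is ENSMUSG00000027296 on chromosome 2, 119742337 to 119751263, and Itpr1 is ENSMUSG00000030102 on chromosome 6, 108213096 to 108551109. Thy1 is ENSMUSG00000032011 on chromosome 9, 44043384 to 44048579. Cdh9 is ENSMUSG00000025370 on chromosome 15, 16728756 to 16857094, and Ebf2 is ENSMUSG00000022053 on chromosome 14, 67233292 to 67430918. Counts of the Purkinje-like class summed to 2692870 UMIs at E16 and 939721 at E18. Over the 11029 genes with enough counts the median log2 ratio was 0.05, and TMM scaling lowered every ratio by 0.10. Across the 3213 genes above 50 CPM the rank correlation between the libraries was 0.933; genes are not independent replicates.

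Genes of Purkinje maturation were higher in the E18 library as a group. The list's median log2 ratio was 0.53 (0.47 to 0.82), at the 100th percentile of 10000 random lists of like expression, with 19 of 20 members above 0 and 5 at least 2-fold higher. The calcium buffer Calb1 stood at 608 and 1080 CPM (log2 0.83, 0.71 to 0.94), Pcp4 at 4652 and 7802 CPM (0.75), Car8 at 586 and 1142 CPM (0.96) and Pcp2 at 1048 and 1393 CPM (0.41). The glutamate transporter Slc1a6 had a log2 ratio of 1.17, and the scaffold gene Shank1 was the exception at -0.47. With every cell thinned to 3000 UMIs the list's median was 0.83.

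Genes of early Purkinje and migrating neurons lay lower in the E18 library, with a median log2 ratio of -0.19 (-0.32 to -0.09) at percentile 1.35 and 5 of 15 members above 0. Log2 ratios were -0.68 for Sox4 and -0.59 for Sox11, transcription factors of immature neurons, -0.68 for Ebf3, -0.23 for Foxp2 and 0.16 for Ebf1. The Purkinje subtype list had a median of -0.23 (-0.50 to -0.03) at percentile 0.09, with 8 of 21 measured members above 0, 2 at least 2-fold higher and 4 at least 2-fold lower. Foxp1 was lower in the E18 library, at 149 against 242 CPM (log2 -0.70, -0.98 to -0.44), while Foxp4 had a log2 ratio of 0.61. The neuropeptide gene Cck stood at 106 and 268 CPM (log2 1.34), En1 had a ratio of -0.78 and En2 of -1.36.

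Synaptic genes differed less in Purkinje-like cells, with a median log2 ratio of 0.14 (0.04 to 0.30, percentile 92.3) and 13 of 20 members above 0; the glutamate receptor subunit Gria2 had a ratio of 0.79 and Syn2 of 0.93. Genes of Purkinje-derived signals had a median of 0.74 (percentile 99.5, 5 of 6 above 0), with the mitogen Shh at 6 UMIs at E16 and 9 at E18 (log2 2.10, 0.45 to 3.88) and Pdgfa at 1.34. The S phase list stood at 0.13 (-0.15 to 0.43, percentile 50.2), glycolysis and hypoxia at 0.11 (percentile 85.2), cholesterol synthesis at 0.04 (percentile 64.0) and neurogenic progenitor genes at 0.33 (percentile 77.7). Dissociation stress genes had a median of 0.68 (0.34 to 1.20, percentile 100), with the immediate early genes Fos at 1.75, Junb at 2.12 and Egr1 at 1.47.

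Genes of other cell types were also higher in the Purkinje-like class of the E18 library. Gliogenesis genes had a median of 1.26 (0.71 to 1.81, percentile 100), with Slc1a3 at 2.33 and Apoe at 1.85; G2M genes had a median of 0.83 (0.49 to 1.30, percentile 99.5), with Top2a at 1.97, and the Shh response list a median of 0.79 (0.41 to 1.15, percentile 99.9). The granule differentiation list went both ways, with 9 of 15 members above 0 and a median of 0.65 (-0.08 to 0.77) that was -0.041 without doublet removal, -0.020 in thinned cells and -0.066 over genes of at least 50 UMIs. Fixed markers of other classes had medians of 0.94 for progenitors or astroglia (percentile 100), 1.18 for granule neurons (percentile 99.9), 0.87 for granule progenitors and 1.61 for unipolar brush cells. The granule progenitor median rests on 4 measured genes and the unipolar brush cell median on 3 (0.10 to 2.33). Levels were low beside free RNA: Apoe stood at 72.4 CPM in the E18 class and 499 CPM in E18 empty barcodes, and Top2a at 16 and 42.2 CPM. The G2M median turned to -0.55 when free RNA was subtracted with barcodes of 10 to 100 UMIs as its source, and it was 0.12 without doublet removal. The gliogenesis median was 0.15 with cells thinned to 3000 UMIs and 0.56 (0.26 to 0.84) over genes of at least 50 UMIs. Haemoglobin genes went the other way, with Hba-a1 at 908 and 133 CPM in Purkinje-like cells (log2 -2.77) and Hbb-bs at -2.48. Of the sex genes, Xist had a log2 ratio of 0.50 and the Y-linked Ddx3y 0.10, Eif2s3y -0.21, Uty -0.14 and Kdm5d -0.98.

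The third comparison asked whether the other classes with at least 100 cells per library showed differences of the same kind. In granule progenitor-like cells, targets and parts of the Shh pathway, which drives their division, were higher in the E18 library. The make-up of this class differed as well: the cluster led by Top2a, Ube2c and Ccna2, genes of dividing cells, held 218 of 650 cells at E16 and 308 of 757 at E18, the cluster with Tbata, Hey1 and Ccnd1 234 and 334, and the cluster led by Pvalb and Fst 198 and 115. The Shh response list had a median log2 ratio of 0.35 (0.26 to 0.44, percentile 100), and of 0.22 (0.18 to 0.38) with the E18 clusters weighted to their E16 shares of the class, with Gli1 at 1.28, Sfrp1 at 0.78 and Ptch1 at 0.50, while Mycn stood at -0.15 and Atoh1 at -0.53 (213 and 148 CPM). Cholesterol synthesis genes had a median of 0.35 (percentile 100, 15 of 15 above 0), and of 0.24 at the E16 shares. The cell cycle medians rested in part on the make-up of the class. S phase genes stood at 0.22 (percentile 100, 19 of 20 above 0), at 0.12 to 0.15 under 4 other settings of cell filtering or centring and at 0.076 at the E16 shares, with medians of 0.45, 0.021 and -0.77 within the Tbata, Top2a and Pvalb clusters. G2M genes stood at 0.12 (percentile 99.9), at 0.00 with at most 5% mitochondrial UMIs per cell, and turned to -0.057 (-0.094 to -0.011) at the E16 shares. Neurogenic progenitor genes lay lower, at -0.70 (-0.99 to -0.41, percentile 0) and at -0.54 at the E16 shares, with Hes5 at -1.04 and Hes6 at -0.62. Within the Tbata, Top2a and Pvalb clusters their medians were -0.022 (-0.51 to 0.40), -0.55 and -0.53. Markers of granule neurons stood at 0.59 (percentile 100), of Purkinje cells at 0.44 (percentile 99.5) and of progenitors or astroglia at -0.23 (percentile 1.22) in this class.

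Of the single genes in granule progenitor-like cells, Pvalb, a calcium-binding protein, stood at 439 CPM at E16 and 47.6 CPM at E18 (log2 -3.20, -3.38 to -3.03). The cluster led by Pvalb and Fst made up 3.81% of all E16 and 2.15% of all E18 cells. Cbln2 had a log2 ratio of -2.19, Pxylp1 -1.65, Spsb4 -1.63 and Pde2a -1.59. Higher in the E18 library were the growth factor receptor Pdgfra (7.95 and 51.2 CPM, log2 2.69, 2.22 to 3.19), Tbata (1.99), C1ql1 (1.60), Cog7 (1.35) and the growth factor Pgf (1.23).

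In granule neuron-like cells the neuropeptide gene Cartpt stood at 9.47 CPM at E16 and 254 CPM at E18, a 26.8-fold difference (log2 4.75, 4.37 to 5.15). Fam210b (1.93), the adhesion molecule Lsamp (1.14), Dynlt1a (1.11) and Cog7 (1.02) followed. The lowest log2 ratios among the 690 candidates of this class were those of Spsb4 (-1.47), the ephrin Efna3 (-1.28), Cbln2 (-1.05), the Wnt inhibitor Sfrp1 (-0.98) and Igfbp2 (-0.97). Granule differentiation genes had a median of 0.17 (0.12 to 0.23, percentile 100, 13 of 17 above 0), with Grin2b at 0.66, Zic1 at 0.27, Neurod1 at 0.17 and Tlx3 at -0.45. Synaptic genes had a median of 0.29 (percentile 100, 15 of 20 above 0). Markers of some other classes were higher too, with medians of 0.96 for Purkinje (percentile 100), 0.85 for progenitors or astroglia (percentile 100) and 2.33 for meningeal fibroblasts (percentile 99.9), while nuclear neuron markers stood at -0.51 (percentile 1.08). The fibroblast median rests on 4 measured genes (1.32 to 3.67). Gliogenesis genes stood at 0.72 in this class, with Apoe at 2.02, and turned to -0.080 after subtraction with the profile of barcodes of 10 to 100 UMIs. Cell cycle medians of 0.19 (S) and 0.23 (G2M, 0.12 at the E16 shares of the clusters) turned to -0.10 and -0.18 without doublet removal.

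The summed neural progenitor or astroglia-like class had higher levels of glial genes in the E18 library. Its make-up differed too: the cluster led by Slc1a3 and Gdf10 held 329 of 668 cells at E16 and 458 of 751 at E18, the cluster with Ptf1a, Msx3 and Neurog2 97 and 82, and the cluster with Rspo1 and Rspo3 87 and 31. The gliogenesis list had a median log2 ratio of 0.46 (0.43 to 0.53, percentile 100, 15 of 18 above 0), and of 0.40 (0.35 to 0.52) with the E18 clusters weighted to their E16 shares. Hepacam, an adhesion molecule of astrocytes, stood at 10.9 and 60.5 CPM (log2 2.48, 2.03 to 2.95), the water channel gene Aqp4 had a ratio of 1.70, Apoe 0.81, Gdf10 0.56 and the glutamate transporter Slc1a3 0.47, while Cst3 had a ratio of -0.42. Cholesterol synthesis genes had a median of 0.53 (0.44 to 0.61, percentile 100, 15 of 15 above 0). G2M genes lay lower, at -0.42 (-0.44 to -0.30, percentile 0), with 1 of 20 members above 0, and at -0.40 (-0.45 to -0.29) with clusters at their E16 shares. Within the clusters of at least 100 cells per library the G2M median was -0.00089 (-0.22 to 0.22) in that led by Slc1a3 and Gdf10 and -0.44 (-0.49 to -0.35) in that led by Gdf10 and Timp4. Dissociation stress genes stood at 0.59 (0.38 to 0.70) and 0.30 (0.06 to 0.48) within these clusters and at 0.24 (0.14 to 0.38) at the E16 shares, against 0.0065 for the summed class. Mural markers in the class stood at 1.54 (percentile 99.95), over 4 measured genes (0.40 to 2.09). Neurogenic progenitor genes had a median of -0.14 (percentile 8.69), and of -0.084 (-0.19 to 0.06) at the E16 shares, in which Neurog2, a factor of neuron production, stood at 50.9 and 15.8 CPM (log2 -1.69) and Hes5 at 0.26. Also lower were the secreted inhibitors Sostdc1 (-2.33) and Sfrp2 (588 and 190 CPM, -1.63), Msx3 (-1.82) and the noncoding H19 (-1.77, -2.44 after subtraction of free RNA and -1.30 in thinned cells). Higher were A830029E22Rik (1.94), Sept4 (1.84), Igfbp7 (1.60) and the glutamate receptor subunit Gria1 (1.59).

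GABAergic interneuron-like cells had higher Tgfb2 in the E18 library (10.0 and 69.0 CPM, log2 2.78), opposite in direction to Purkinje-like cells. The transcription factor Nfix stood at 189 and 591 CPM (log2 1.64, 1.46 to 1.83), and the matrix proteoglycan Vcan (1.57), Nebl (1.48) and Tpbg (1.45) were higher too. Cartpt was lower here, at 31.8 against 173 CPM (log2 -2.44), with Ucma (-1.77), Laptm4b (-1.68), the transcription factor En1 (-1.60, and -2.28 in thinned cells) and Rnd3 (-1.37). Synaptic genes had a median of 0.24 (percentile 100), while the Purkinje subtype list stood at -0.67 (percentile 0), early neuron genes at -0.29 (percentile 0.07) and neurogenic progenitor genes at -0.37 (percentile 0.5). Markers of some other classes were higher here too, with medians of 0.95 for Purkinje (percentile 100), 1.15 for granule progenitor (percentile 99.7) and 2.22 for unipolar brush cells (percentile 99.9), while granule neuron markers stood at -0.47 (percentile 0.44). The granule progenitor and unipolar brush cell medians each rest on 3 measured genes. Of the latter (0.78 to 3.72), 2 were at least 2-fold higher and 1 at least 2-fold lower.

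Unipolar brush cell-like cells had the neuropeptide genes Grp at 3.27 and 174 CPM (4 and 263 UMIs, log2 5.74, 4.36 to 7.62) and Tac2 at 11.5 and 322 CPM (log2 4.81). Dact1 (2.70), Pkib (2.40, and 3.44 in thinned cells) and Arpp21 (1.91) were higher as well. A further neuropeptide gene, Tac1, was lower in the E18 library (57.3 and 7.29 CPM, log2 -2.97), as were Chac1 (-2.17), Ucma (-1.93), Gas1 (-1.72) and Pmepa1 (-1.59). Synaptic genes had a median of 0.32 (percentile 99.9), with Syn2 at 1.85. Dissociation stress genes stood at 0.69 (0.24 to 0.94, percentile 100, 6 of 14 at least 2-fold higher), Purkinje markers at 1.16 (percentile 100) and progenitor or astroglia markers at 1.00 (percentile 99.8), and nuclear neuron markers at -0.64 (percentile 1.43). The S phase median of -0.32 (percentile 0.32) turned to 0.12 without doublet removal, and the gliogenesis median of 1.00 turned to -0.41 after subtraction with the profile of barcodes of 10 to 100 UMIs.

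Purkinje maturation genes had medians above 0 in all 5 of these classes as well, from 0.30 in progenitors or astroglia to 0.60 in unipolar brush cell-like cells. Levels in those cells were far below the Purkinje-like class: Calb1 stood at 8.17 and 19.2 CPM and Pcp2 at 15.8 and 30.9 CPM in granule neuron-like cells. In empty barcodes Calb1 stood at 264 and 473 CPM. After subtraction of free RNA in proportion to haemoglobin and Ttr, the median turned to -0.11 in granule progenitors and -0.030 in progenitors or astroglia, and remained 0.54 in Purkinje-like cells. With the lower estimate, from the UMIs of an empty barcode per cell, it was 0.37 (-0.02 to 0.81) in granule progenitors and 0.10 (-0.10 to 0.43) in progenitors or astroglia. With the profile of barcodes of 10 to 100 UMIs it was 0.16 and 0.063.

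**Figure D4:**
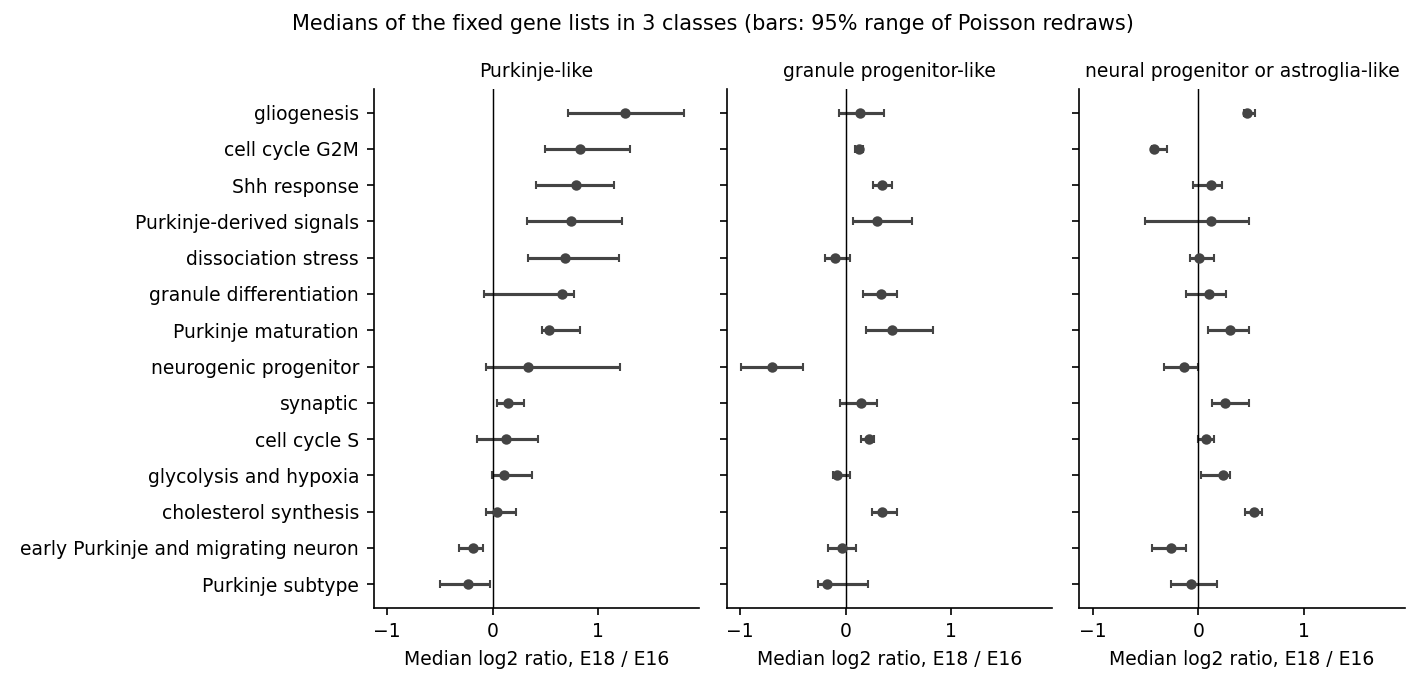
Median log2 ratio, E18 over E16, of the fixed gene lists in Purkinje-like, granule progenitor-like and neural progenitor or astroglia-like cells, with the 95% range of Poisson redraws as bars. The G2M median was 0.83, 0.12 and -0.42 in these classes (-0.057 in the second with clusters at their E16 shares), and the gliogenesis median 1.26 in the first and 0.46 in the last.

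The fourth comparison asked how unlike Purkinje-like cells were among themselves at each age. After thinning to 3000 UMIs, the variance over the mean (Fano factor) of Purkinje subtype genes was compared with 200 genes of like mean. At E16, 16 of the 20 measured subtype genes lay above the 95th percentile of such genes in 349 cells, and at E18 6 of 12 did in 85 cells. In draws of 85 E16 cells, 7 to 10 genes passed, of 12 to 14 that could still be measured. Foxp1, Ebf2, Rorb, Epha4, Cdh9 and Cck passed in both libraries, and at 1500 UMIs per cell 1 gene did. Foxp1 had a Fano factor of 3.82 at E16 against a median of 1.06 for like genes, and of 2.73 against 1.01 at E18. The Fano factor of Cck was 4.16 at E16 and 14.8 at E18. Across the 12 genes measured in both, the rank correlation of percentiles was 0.442, and up to 0.802 with another thinning seed. Over all 4103 genes measured in both, 81 passed in both, against 11.5 if the libraries were independent. Those furthest above their reference genes were Malat1, Sst, Pcp4, Pcp2, Nnat and Actb, and markers of other classes such as Fabp7, Neurod2 and Mfap4 were among the 81. All of those furthest above but Sst shared 1 reference set, with a median Fano factor of 1.21 at E16. Their E16 means ran from 3.05 (Pcp2) to 61.5 UMIs (Malat1). They were thus not compared with genes of like mean, and their rank is not read. The figure of 11.5 allows for no free RNA or doublets in both libraries, so the excess is not read as heterogeneity of Purkinje cells alone.

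Sub-clusters were found on a random 50% of each cell's UMIs and subtype genes were read from the rest. Purkinje-like cells fell into 11 sub-clusters at E16 and 5 at E18, and into 9 to 11 and 4 to 6 over the seeds. Foxp1 stood at 1116 CPM in an E16 sub-cluster of 41 cells, 7.88-fold over the other cells (6.30 to 9.86), and at 428 CPM in an E18 sub-cluster of 20 cells, 6.16-fold (3.68 to 10.5). Foxp2 was more even, at 1.76-fold and 1.39-fold in its highest sub-clusters. Rorb reached 10.3-fold at E16 in 19 cells, and Cck reached 6.14-fold at E16 and 8.41-fold at E18. Epha4 reached 3.69-fold and 3.72-fold, and Ebf2 2.64-fold and 2.85-fold. In each case the sub-cluster with the highest level was picked, which alone gave medians of 1.5-fold at E16 and 1.33-fold at E18, and at most 2.17-fold, in simulated cells of 1 profile. The clustering also split such simulated cells, into 10 and 4 sub-clusters, so the number of sub-clusters is no measure of heterogeneity.

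**Figure D5:**
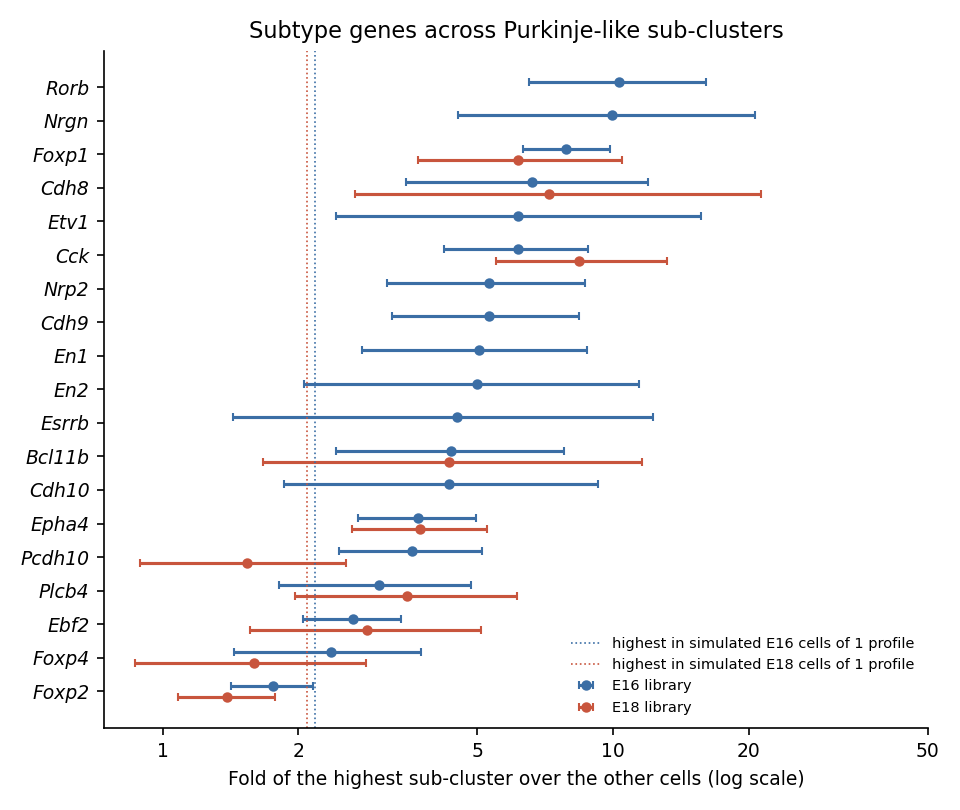
Level of subtype genes in the Purkinje-like sub-cluster with the highest level, relative to the other Purkinje-like cells, at E16 and E18, with 95% intervals as bars. Foxp1 reached 7.88-fold at E16 and 6.16-fold at E18, and Foxp2 1.76-fold and 1.39-fold.

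The fifth comparison took the transcription factors Foxp1 and Foxp2, known to mark embryonic Purkinje subtypes. With cells thinned to 3000 UMIs, Foxp2 was seen in 84.0% of E16 Purkinje-like cells (293 of 349, 79.7 to 87.6%) and 81.2% of E18 cells (69 of 85, 71.2 to 88.8%), against 4.74% and 4.13% of granule neuron-like cells. Foxp1 was seen in 28.4% (23.7 to 33.4%) and 16.5% (9.31 to 26.1%), against 15.3% and 15.7% in granule neuron-like cells. The E18 Foxp1 share in this draw was thus within counting error of the granule neuron-like share; averaged over every possible thinning it was 27.6% at E16 and 23.5% at E18, beside 15.4% and 14.4%. Cells with both made up 24.1% and 16.5%, against 1.03% and 0.759% of granule neuron-like cells; averaged over every possible thinning the Purkinje-like shares were 24.3% and 20.3%, beside 23.3% and 19.8% if the factors were seen independently. Thinning left out 10 E16 and 3 E18 Purkinje-like cells and 12 and 30 granule neuron-like cells. Without thinning, at median depths of 7479 and 10399 UMIs, Foxp1 was seen in 39.6% and 42.0% and Foxp2 in 93.0% and 98.9% of Purkinje-like cells. Granule neuron-like cells, at 7614 and 7451.5 UMIs, then had Foxp1 in 33.1% and 30.9% and Foxp2 in 10.1% and 9.38%. No order between the ages is read from the Foxp1 shares, since the unthinned order runs against the CPM.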

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

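The tests of dilution and of free RNA below and the looser naming rule were chosen after the results were seen; the tests on every barcode and on empty barcodes were set earlier, although the window of totals taken as empty was moved later.

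The share of Purkinje-like cells in the E18 library was 0.238 times that at E16. Purkinje RNA (Pcp2, Car8, Calb1, Foxp2 and Rora) over every barcode had a ratio of 1.07 and in empty barcodes of 1.14 (0.817 with the first window), so cells lost at the barcode filters or lysed with their RNA left behind may account for part of the lower share. The sum over every barcode includes the empty ones, so it alone does not separate the 2. In barcodes of at least 500 UMIs, before the other filters, the ratio was 0.771 (0.753 to 0.789), nearer to the 0.672 of kept cells of every class than to 1.07. Filters above that total thus account for little of the gap in RNA between kept cells and every barcode. These tests also count RNA, not cells: Calb1 had a higher CPM within the class, while Foxp2, closer to even there, had a ratio of 0.583 over every barcode. Dilution by later-born cells was read from nuclear neuron-like cells, whose ratio was 0.137 as named and 0.769 under the looser rule. That rule added the cluster with Tal2 and Tfap2d, taken as midbrain genes. Nuclear neuron markers summed over kept cells, a sum that counts every cluster, had a ratio of 0.956 (0.892 to 1.02), and dilution stays open because the naming decides it. Loss during dissociation and a difference between the ages themselves were not tested and stay open.

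Gliogenesis and G2M genes were higher in the Purkinje-like class of the E18 library, with medians of 1.26 and 0.83. For gliogenesis every subtraction run left the median above 0, at 1.18 (0.45 to 1.65) with the empty-barcode profile, 1.16 (0.63 to 1.72) with barcodes of 10 to 100 UMIs and 1.59 (0.92 to 1.89) with the lower estimate. The rule written for this test also asked for an interval above 0 in thinned cells, which was not met, so the test could not tell. For G2M the same subtractions gave 0.94 (0.35 to 1.71), -0.55 (-2.85 to 0.12) and 0.89 (0.59 to 1.52), so there too free RNA cannot be told apart from RNA of the cells. Over genes of at least 50 UMIs the gliogenesis median was 0.56 (0.26 to 0.84), so genes with few counts carry part of it. With every cell thinned to 3000 UMIs, which removes no free RNA but leaves few counts, both intervals included 0 (0.15, -0.10 to 0.94, and 0.72, -0.26 to 1.43), so at equal depth neither difference was resolved. Without doublet removal the gliogenesis median was 1.27 (0.65 to 1.60) and the G2M median 0.12 (-0.28 to 0.25), so keeping called doublets did not raise G2M and left gliogenesis about the same. Doublets left after Scrublet and an age difference were not themselves tested and stay open.

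Purkinje maturation genes were higher in the E18 library in 5 other classes too. After subtraction of the empty-barcode profile the highest of their medians was 0.13 (-0.08 to 0.34), in granule neuron-like cells, and that of Purkinje-like cells was 0.54. At the shares used for granule neuron-like cells, 7.34% at E16 and 10.1% at E18, this took away more Calb1 and Pcp2 than those cells held. Counts below 0 were set to 0, so these medians cannot decide whether free Purkinje RNA was the source. With the lower estimate of free RNA, from the UMIs of an empty barcode per cell, the median was 0.52 (0.25 to 0.67) in granule neuron-like and 0.43 (0.07 to 0.64) in interneuron-like cells, against 0.06 in unipolar brush cell-like cells. The outcome thus rests on the amount subtracted, and a higher level in those cells themselves cannot be told apart from free RNA.

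A signal outside the comparisons was haemoglobin RNA in empty barcodes, which made up 1.09% of their UMIs at E16 and 0.269% at E18. Sex-linked RNA was also outside the comparisons: among cells with Xist or a Y-linked gene but not both, 40.5% had Xist at E16 (38.9 to 42.2%) and 62.4% at E18 (60.9 to 63.9%). Cells with both, 163 at E16 and 260 at E18, were left out of these shares. The unnamed cluster led by Lhx2, Lhx9, Tal2 and Tfap2d held 0.212% of E16 cells (11 cells) and 1.03% of E18 cells (55 cells); a cluster mostly of 1 library may be a feature of that library, and its inclusion moved the nuclear neuron-like ratio from 0.137 to 0.769.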

How the results depend on the processing

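No paired analysis was possible because the groups share only replicate number 1 and no result comes from a test. E16 replicate 2 in place of replicate 1 was not run, as it was not analysed here. The looser naming rule, the per-cell call, the profile of barcodes of 10 to 100 UMIs, the free RNA estimate per empty barcode, the untrimmed free RNA share, the equal cell numbers, the mean over thinnings, the clustering without markers and the clusters at their E16 shares were chosen after seeing the data. Under the settings chosen beforehand 967 values stayed within their tolerance, 78 moved beyond it and 7 reversed, the tolerance being the 95% interval of the reported value or, for values with none, 1.5 times the value and for the rank correlation its SD over the seeds; under the added ones the counts were 206, 37 and 7. The Purkinje-like share ratio lay between 0.187 and 0.250 under the settings chosen beforehand, and was 0.233 without markers in the clustering. A call by 3 or more Purkinje markers per cell at 3000 UMIs gave 0.454, with 18 of 286 E16 calls and 54 of 134 E18 calls outside the Purkinje-like cluster, 0 and 9 of them in granule neuron-like cells. Free RNA alone would give 23.0 and 79.8 calls there by the higher estimate of its share, more than were seen. By the lower it would give 0.510 and 2.63, fewer than were seen. The higher share lies above those that took more Calb1 and Pcp2 from granule neuron-like cells than these held. How many calls outside the cluster stem from free RNA is thus not known, and 0.454 is not read as a ratio of Purkinje cells.

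The granule neuron-like share ratio was 1.87 at resolution 0.5, 1.34 at resolution 2 and 1.34 with at most 5% mitochondrial UMIs, where the interneuron-like ratio was 0.506. Looser naming gave 0.769 for nuclear neuron-like and 0.956 for unipolar brush cell-like cells, because it added clusters. The Purkinje maturation median was 0.43 with TMM scaling, which shifts every gene alike, and 0.83 with thinned cells, where gliogenesis in astroglia was 0.42, S phase in granule neuron-like cells -0.020 and Glra2 in Purkinje-like cells 0.064. Thinning also moved Itpka from 3.21 to 1.51, Gm15594 to 2.57, Grin2b from -0.98 to -2.82, En1 in interneuron-like cells from -1.60 to -2.28 and Pkib from 2.40 to 3.44. These thinned ratios of single genes come from 1 random draw, and in another draw Glra2 was lower at E18. Without doublet removal the granule neuron-like medians were -0.18 (G2M), -0.10 (S) and 0.26 (granule differentiation), and S phase in unipolar brush cell-like cells was 0.12. The G2M median of granule progenitors was 0.0022 with at most 5% mitochondrial UMIs and 0.0085 with centred components. With the E18 clusters of a class at their E16 shares it turned to -0.057, Shh response there was 0.22 and gliogenesis in astroglia 0.40, because the make-up of the classes differed.

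S phase in granule progenitors was 0.118 with 2000 UMIs, 0.129 without doublet removal, 0.130 with at most 5% mitochondrial UMIs and 0.147 with centred components, against 0.22. Subtraction of free RNA moved H19 to -2.44 (thinning moved it to -1.30) and turned Purkinje maturation to -0.11 in granule progenitors and -0.030 in astroglia. With barcodes of 10 to 100 UMIs as its source, G2M was -0.55 in Purkinje-like and -0.36 in granule neuron-like cells, S phase in the latter -0.078, and gliogenesis -0.080 there and -0.41 in unipolar brush cell-like cells. Except where a reason is given, the cause was not tested.

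Depth and cell number set the heterogeneity counts. With as many E16 as E18 cells, 8, 7, 7, 9 and 10 of 12 to 14 measured subtype genes passed at E16 in place of 16 of 20. At 1500 UMIs 1 gene passed in both libraries, Foxp1 was seen in 19.5% and both factors in 14.8% of E16 cells, and Foxp2 in 67.1% at E16 and 65.9% at E18. Without thinning Foxp1 was seen in 39.6% and 42.0%, Foxp2 in 93.0% and 98.9%, and both in 37.3% and 42.0%. The rank correlation of Fano percentiles was 0.802 and 0.762 with seeds 3 and 4 against 0.442. With 88 Purkinje-like cells at E18, genes under about 10 UMIs there could not be read.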

Other observations

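Unnamed clusters differed in size between the libraries as well. A cluster led by Cbln2, Sfrp1, Rorb and Nr2f2 held 3.75% of E16 cells (195) and 0.784% of E18 cells (42). Cells with Olig1, Olig2 and the GABA transporter gene Slc6a11 went the other way, at 0.885% and 2.61%, beside the oligodendrocyte lineage-like share of 0.577% and 1.90%. An astroglia-like cluster led by the Wnt enhancers Rspo1 and Rspo3 held 1.67% and 0.579%. Clusters of similar share in both libraries were those with Lhx5, Tfap2b, Neurog1 and Pax2 (2.0% and 2.09%) and with Tlx3, Pmaip1 and the acetylcholine receptor subunit Chrna3 (6.54% and 5.28%). A cluster with Otx2, Cxcl14 and Top2a made up 4.64% and 2.95%.

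RNA of fixed markers over every barcode gave ratios that need no naming of cells. Oligodendrocyte lineage markers had a ratio of 2.56 (2.45 to 2.67), endothelial markers 1.71, meningeal fibroblast markers 1.59, mural markers 1.56 and microglia markers 1.32. Interneuron markers had a ratio of 0.719 (0.699 to 0.740), choroid plexus markers 0.696 and erythroid markers 0.307. Ratios for granule progenitor, granule neuron and nuclear neuron markers were 1.02, 1.09 and 0.980. Among genes that varied more than like genes between Purkinje-like cells in both libraries and stand on no list, the secretogranin gene Scg2 had a Fano factor of 2.21 at E16 and 5.43 at E18, Syt4 1.79 and 6.42, and Brinp3 2.62 and 4.06; these were picked after their values were seen.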
